A study of Solanum tuberosum with 48 samples.

How the data were processed

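The study measured total RNA of inoculated potato leaves on POCI arrays in a 1-colour design, with 48 arrays of 48 plants. The groups were the 12 combinations of 2 genotypes (Rywal and NahG-Rywal), 2 inocula (PVY and mock) and 3 days (1, 3 and 6 dpi), with 4 plants each, which the labels call biological replicates. Per the labels' protocols, the RNA was spiked with a commercial control mix, amplified as antisense RNA and labelled. The labels' field for the dye names Cy3 while the protocol text names Cy-5, and which is right stays open. This changes no comparison, since all arrays carry 1 colour. The labels' processing notes name limma, with no version.

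Each array came as a deposited scanner table with the foreground intensity, the local background intensity and a weight of 0 or 1 for each of 45220 spots, per the file headers not yet normalized. The image analysis program and scanner settings are not given in the sources used here. From the values, the weight was 1 almost only where foreground exceeded 1.5 times background, so weight 1 was read as above background. The series also held a deposited matrix of the authors' processed values, read as log2 because it followed the log2 scanner intensities. Each of its 48 columns matched its own array best, with a lowest rank correlation of 0.9933 and column medians of 8.19 to 8.9, so its columns were not centred on 0. How the authors corrected background, normalized and averaged these values is not given in the sources used here. A deposited table by the authors gave log2 fold changes and adjusted p-values (p-value unit per the file headers) for the 6 comparisons of PVY with mock leaves. Its adjustment method is not stated.

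The main values were made here from the scanner tables with limma 3.58.1 in R 4.3.3. Background was corrected with normexp (offset 50) on all spots, and 1417 control spots and 1769 spots without an ID were then left out. The 42034 plant probes were quantile normalized between arrays and taken to log2. Spots with weight 0 whose foreground was above 1.5 times background were set to missing, which concerned 15527 probes on at least 1 array and 127 to 2486 probes per array. Probes above background on fewer than 4 arrays were left out, so 41468 remained. Each comparison tested those with values in all its groups. No probe ID occurred on more than 1 plant spot after this step.

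One linear model with 12 group means was fitted to all 48 arrays (36 residual degrees of freedom), and limma's moderated tests were adjusted by the Benjamini-Hochberg method within each comparison at a threshold of 0.05. The 14 comparisons were the 6 responses (PVY minus mock), the 3 genotype differences of the response (NahG-Rywal response minus Rywal response), the 3 genotype differences in mock leaves (NahG-Rywal minus Rywal), and a test of change over the 3 days for each genotype. Positive values are therefore higher in PVY leaves or in NahG-Rywal. Standard errors are those of the moderated test. A count of independent lists is the product of the call numbers divided by the number of probes tested in both. Quantile normalization gives every array the same distribution, so all changes are relative to it.

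Probes to name were set by a rule fixed before the data were examined: the 8 largest rises and falls per response, with every PVY plant on the same side of the mock mean, and the 5 largest differences in each direction per genotype comparison. The rule asked for probes with a gene description. The files hold none, and 0 probe names matched the reference table of potato gene names used here, so the rule was applied to all probes and the text names at most 2 per direction. For the same reason the 34 gene lists fixed in advance could not be filled, and 0 were tested. For the named probes of pairwise comparisons, each group had at least 1 array above background, and folds were given as fitted; where only some arrays of a mock group were above background, the size of the fold is less certain. Differences of responses that rest on a group with 0 arrays above background are not settled in size.

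The fitting code was tested on simulated data made from the real arrays' spread, with 200 of 42034 probes changed. For the Rywal response at 3 dpi it recovered 52%, 86%, 96% and 100% of changes of 0.5, 1, 2 and 3 (log2), with 12 false calls among 41834 unchanged probes. For the genotype difference of the response at 3 dpi it recovered 32%, 64%, 94% and 100%, with 10 false calls. For change over time in Rywal it recovered 34%, 68%, 96% and 100%, with 4 false calls. The simulated noise was independent between probes, with no shift between sets of arrays. The real comparisons called far more probes, so these numbers of false calls need not hold for them. On 26343 probes without missing values the log10 p-values equalled those of limma's own fit within 1.5e-13. Replicate arrays were compared first: 0 pairs held identical values, and log2 foreground correlated at 0.961 to 0.9976 within groups.

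Alternatives fixed before the data were examined were no background subtraction, each array's 75th percentile set equal in place of quantile normalization, no filter on dim probes, the authors' processed values, a fit to only the groups compared, the plant number as a block, and each array left out in turn. Chosen after seeing the data were keeping bright spots of weight 0, testing only the 23894 probes above background on all arrays, using the NahG-Rywal mock arrays of 1 and 3 dpi for those of 6 dpi, and removing the trend along the number that ends a probe ID. Removing that trend set each array's median deviation from the probe means to 0 within bins of that number and of mean level. It therefore also removed overall and level-dependent shifts of an array. Figures were drawn with matplotlib 3.10.9.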

Results

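Transcript levels were measured in inoculated potato leaves on 48 arrays, 1 array per plant. The leaves came from cultivar Rywal and from NahG-Rywal, the same cultivar carrying the bacterial salicylate hydroxylase gene NahG, whose product degrades salicylic acid. Leaves had been rubbed with sap of tobacco infected with potato virus Y (PVY) or with water (mock) and were taken at 1, 3 or 6 days post inoculation (dpi). Each of the 12 combinations of genotype, inoculum and day held 4 plants. Because mock leaves received water, every response given here (PVY minus mock, log2) also holds any effect of the tobacco sap. Of 42034 plant probes per array, 33383 to 39294 were above the local background, which was 79.4% to 93.5%. Median foreground intensity per array ran from 131 to 375 and median background intensity from 6.58 to 19.6. The number of arrays limits the precision, with 4 plants per group. The files do not pair probe IDs with genes, so probes are given by ID, and at most 2 that rose and 2 that fell are named per comparison.

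The arrays did not differ by inoculum alone. In 4 groups, PVY leaves of Rywal at 1 and 3 dpi, PVY leaves of NahG-Rywal at 1 dpi and mock leaves of NahG-Rywal at 6 dpi, the upper spread of foreground intensity (75th percentile minus median, log2) was 2.59 to 2.85 on 16 arrays. On the other 32 arrays it was 2.17 to 2.47. The same 16 arrays also stood apart by the number that ends a probe ID. For this, levels were taken relative to each probe's mean over all arrays, for probes with a mean above 9 (log2). High-number probes (over 1000) were then shifted against low-number probes (up to 120) by 0.09 to 0.56 (log2) on these 16 arrays. On the other 32 arrays the shift was -0.3 to 0.02. It compares arrays and does not show which probes were brighter on an array. The files do not define the number that ends an ID, and they give no slide or scan date.

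**Figure D1:**
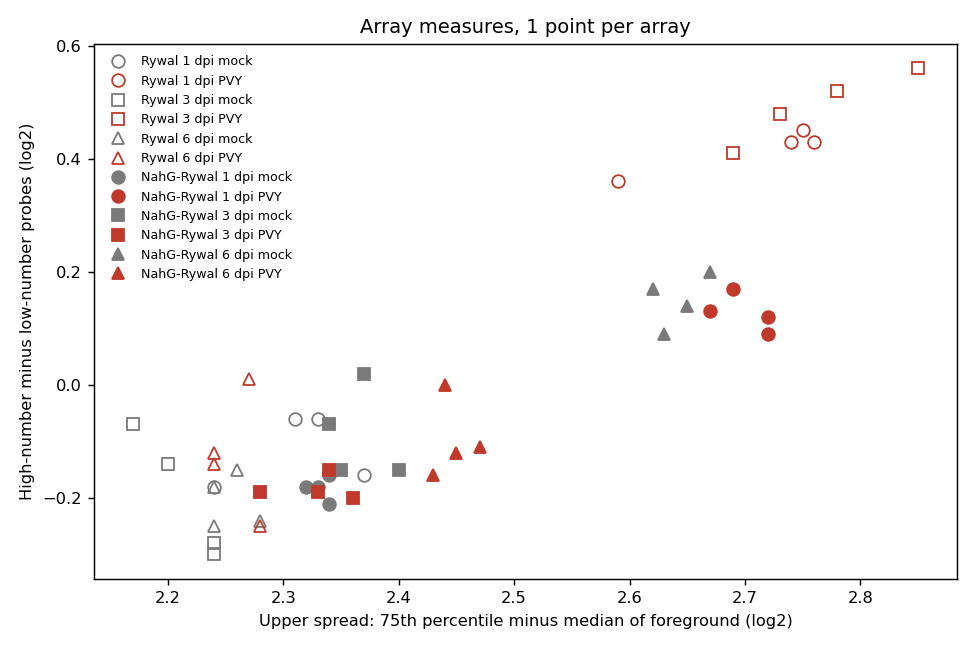
Upper spread of foreground intensity (log2, horizontal) against the shift of high-number relative to low-number probes (log2, vertical), 1 point per array. The shift is in levels relative to each probe's mean over all arrays. Open points are Rywal and filled points NahG-Rywal, with grey for mock and red for PVY. The 16 arrays of 4 groups sit between 2.59 and 2.85 on the horizontal axis, and the other 32 between 2.17 and 2.47.

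The first question was how leaves of Rywal, in which PVY triggers a hypersensitive response, changed over the first days. At 1 dpi, 24139 of 41456 probes tested differed between PVY and mock leaves, 13242 higher and 10897 lower. At least 2-fold changes covered 2556 probes that rose and 3712 that fell, and at least 8-fold changes covered 35 and 77. The largest rise was that of ACDA00263F11.T3m.scf_336, by 4.55 (standard error, SE, 0.31, adjusted p = 3.2e-15), from 7.23 ± 0.62 to 11.79 ± 0.29 (normalized log2 intensity, SD, n = 4 per group). MICRO.15697.C1_1073 rose by 4.54. MICRO.6414.C1_647 fell by 4.39 (SE 0.24, adjusted p = 8.8e-18), from 12.86 ± 0.42 to 8.47 ± 0.39, and MICRO.3496.C1_862 fell by 4.33. With each array's 75th percentile set equal in place of quantile normalization, 9052 probes were higher and 14190 lower. A fit to the 8 arrays of this comparison alone called 18203 probes. All PVY arrays of this comparison belonged to the 16 with the wider spread, and none of its mock arrays did. In NahG-Rywal mock leaves at 6 dpi, which shared that spread, MICRO.6414.C1_647 averaged 9.58 ± 0.13 and MICRO.3496.C1_862 6.34 ± 0.04. These were the lowest mock levels of both probes, so their falls may hold part of that shift. The named rises, at 9.56 and 8.95 there, stayed below their Rywal PVY levels.

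At 3 dpi, 25595 of 41464 probes differed in Rywal, 14120 higher and 11475 lower, of which 3648 rose and 4677 fell at least 2-fold. STMIP09TV_659 rose by 5.79 (SE 0.36, adjusted p = 8.8e-17), from 6.67 ± 0.35 in mock leaves to 12.46 ± 1.04 in PVY leaves (SD, n = 4 each), and MICRO.13306.C1_308 rose by 4.6. MICRO.6414.C1_647 again had the largest fall (-5, SE 0.24, adjusted p = 1.1e-19), followed by MICRO.15720.C1_569 (-4.78, measured in 3 of the 4 PVY plants). With the 75th percentile set equal, 10210 probes were higher and 12982 lower. As at 1 dpi, all PVY arrays and no mock array had the wider spread.

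At 6 dpi the Rywal response was smaller, with 12882 of 41456 probes past the test, 5806 higher and 7076 lower. Large changes were mostly rises: 1143 probes rose and 419 fell at least 2-fold, while 80 rose and 0 fell at least 8-fold. The largest fall was that of BF_LBCHXXXX_0035A04_T3M.SCF_21 (-2.33), and MICRO.9043.C1_713 fell by 2.13. STMIP09TV_659 again rose most, by 6.45 (SE 0.36, adjusted p = 5.3e-16), from 6.36 ± 0.14 to 12.81 ± 0.46 (SD, n = 4 each). MICRO.11018.C1_851 rose by 6.26 (SE 0.62, adjusted p = 8.1e-10), from 6.82 ± 0.44 to 13.08 ± 0.53. A fit to the 8 arrays of this comparison alone called 7101 probes.

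**Figure D2:**
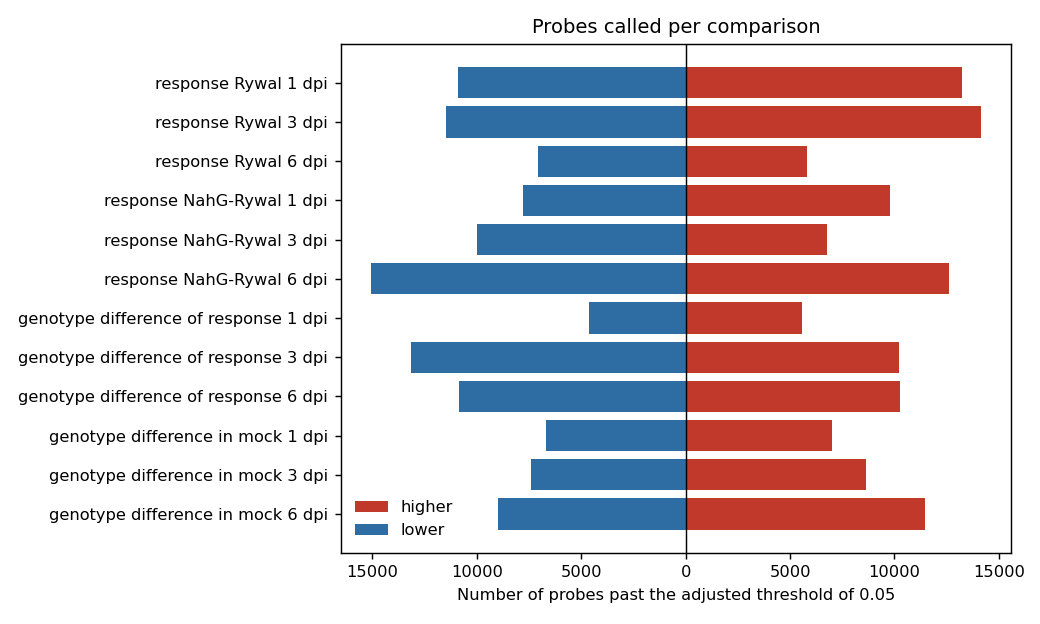
Number of probes past the adjusted threshold of 0.05 per comparison, bars to the right for higher and to the left for lower. The NahG-Rywal response at 6 dpi has 27662 calls (25382 with its mock arrays replaced by those of 1 and 3 dpi), the Rywal response at 3 dpi 25595 and the Rywal response at 6 dpi 12882, the fewest of the 6 responses.

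The same comparisons in NahG-Rywal addressed which part of the response takes place when salicylic acid is degraded. At 1 dpi, 17619 of 41462 probes differed, 9805 higher and 7814 lower, or 6966 and 7074 with the 75th percentile set equal. A fit to only the arrays of this comparison called 21189, above the 18203 of the same fit for Rywal at 1 dpi. Which genotype had more calls at 1 dpi is therefore not settled. Of the 17619, 276 rose and 2055 fell at least 2-fold, and 0 rose and 18 fell at least 8-fold. MICRO.3540.C6_22 rose by 2.55 (SE 0.28, adjusted p = 1.5e-09), and MICRO.66.C1_41 fell by 4.4 (SE 0.23, adjusted p = 4.7e-17), from 12.58 ± 0.09 to 8.19 ± 0.08 (SD, n = 4 each). MICRO.15720.C1_569, which also fell in Rywal, fell by 3.91. Without virus, in NahG-Rywal mock leaves at 6 dpi, MICRO.66.C1_41 was at 8.01 ± 0.16 and MICRO.15720.C1_569 at 6.8 ± 0.11. Both levels were close to those of the PVY leaves at 1 dpi, so these falls are not particular to PVY leaves. The rise of bf_cswcxxxx_0005c09.t3m.scf_66 (2.4, adjusted p = 1.5e-02) did not pass the test with PVY plant 1 left out: it was then 1.82 (adjusted p = 8.5e-02, over all alternatives 2.2e-03 to 8.5e-02). The PVY arrays of this comparison had the wider spread and the mock arrays did not.

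At 3 dpi the NahG-Rywal response had the opposite balance of large changes: 1660 probes rose and 741 fell at least 2-fold, and 261 rose and 0 fell at least 8-fold. Neither its PVY nor its mock arrays had the wider spread. In all, 16762 of 41468 probes differed, 6767 higher and 9995 lower. With the 75th percentile set equal, 25485 differed, 5234 higher and 20251 lower. With the trend along the ID number removed, a step that by itself favours an even balance, 8061 were higher and 7977 lower. STMIP09TV_659 rose by 6.95 (SE 0.36, adjusted p = 1.7e-17), from 6.27 ± 0.14 to 13.23 ± 0.13 (SD, n = 4 each), and MICRO.9396.C1_1045, above background on 2 of the 4 mock arrays, rose by 6.73 (SE 0.51, adjusted p = 2.5e-13). MICRO.590.C10_417 fell by 2.85 and bf_lbchxxxx_0057e06.t3m.scf_300 fell by 2.75.

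At 6 dpi NahG-Rywal had the most changes of the 6 responses in this fit, 27662 of 41462 probes, 12600 higher and 15062 lower. At least 2-fold, 4910 rose and 5117 fell, and at least 8-fold, 769 rose and 295 fell. MICRO.1588.C6_734 rose by 7.95 (SE 0.58, adjusted p = 5.8e-15), from 6.28 ± 0.14 to 14.23 ± 0.12 (SD, n = 4 each). MICRO.8335.C3_1111 rose by 7.94 (SE 0.5, adjusted p = 3.8e-16), from 6.33 ± 0.32 to 14.27 ± 0.07, and was above background on 2 of the 4 mock arrays. bf_cswbxxxx_0027a10.t3m.scf_145 fell by 5.36 (SE 0.6, adjusted p = 4.4e-10), and SDBN003C07u.scf_513 fell by 5.1. Here the mock arrays had the wider spread and the PVY arrays did not. With the NahG-Rywal mock arrays of 1 and 3 dpi in their place, a setting chosen after the values were seen, 25382 probes differed, below the 25595 of Rywal at 3 dpi. With the 75th percentile set equal, 9972 were higher and 19046 lower. With the trend along the ID number removed, which by itself favours an even balance, 13915 were higher and 13615 lower.

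**Figure D3:**
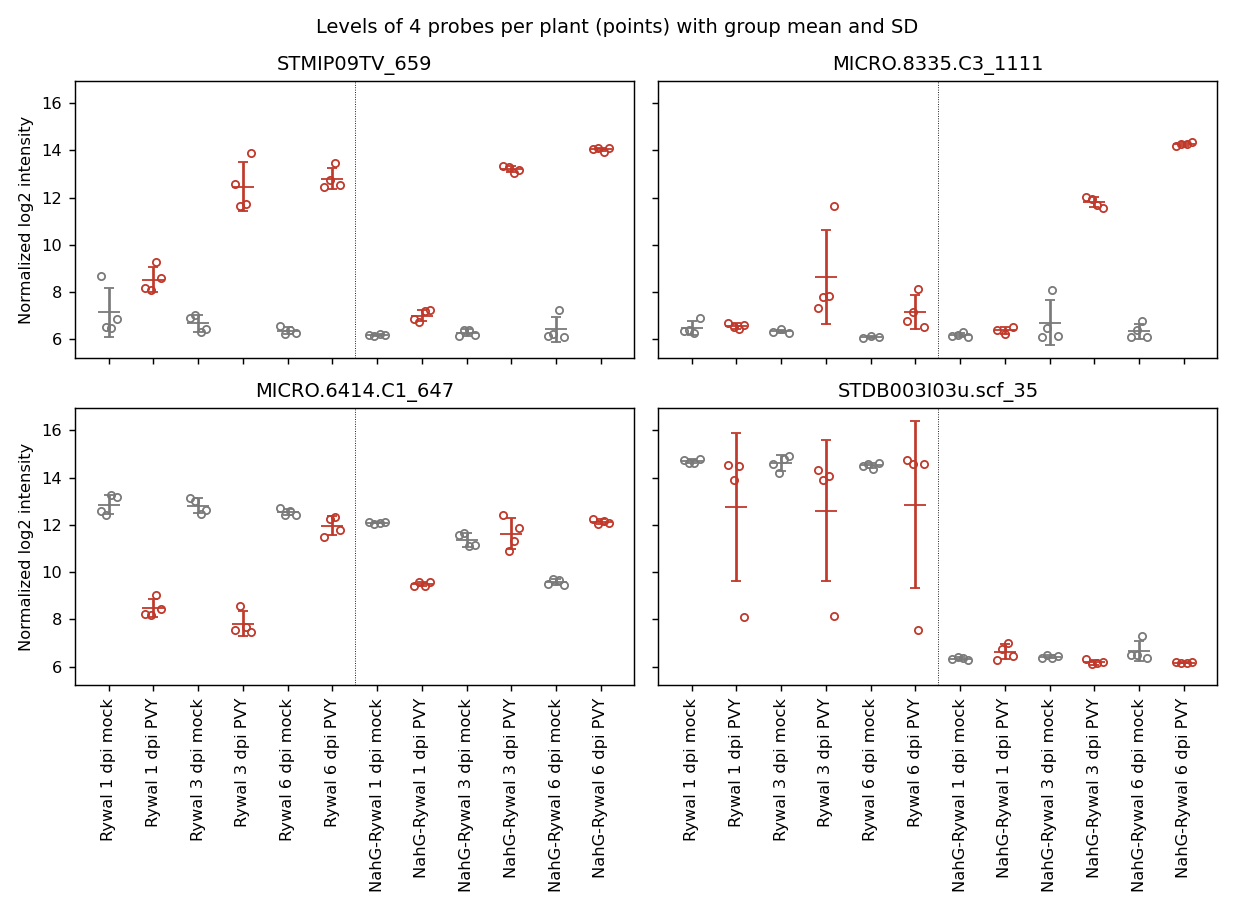
Normalized log2 intensity (vertical) of 4 probes in each of the 12 groups (horizontal), with a point per plant, the group mean and SD bars, red for PVY and grey for mock. STMIP09TV_659 averages 12.46 and 12.81 in Rywal and 13.23 and 14.04 in NahG-Rywal PVY leaves at 3 and 6 dpi. STDB003I03u.scf_35 is above 13 in Rywal except in 3 PVY plants at 7.54 to 8.13. In NahG-Rywal it is at 7.3 or lower.

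The responses fell into 2 kinds when log2 fold changes were correlated across probes, which are not independent replicates; 15 pairs of responses were compared, none with arrays in common. Rywal at 1 and 3 dpi and NahG-Rywal at 1 dpi resembled each other (r = 0.83, 0.74 and 0.82). Of the probes called in both Rywal responses at 1 and 3 dpi, 9923 rose in both, against 4508 for independent lists, and 9087 fell in both, against 3016. The responses of Rywal at 6 dpi and of NahG-Rywal at 3 and 6 dpi formed the other kind (r = 0.67 for Rywal 6 dpi with NahG-Rywal 3 dpi, 0.6 for the 6 dpi responses and 0.82 for NahG-Rywal 3 with 6 dpi). Between the kinds, r was 0.02 for Rywal 1 and 6 dpi, 0.32 for Rywal 3 and 6 dpi and -0.47 for Rywal 1 dpi and NahG-Rywal 6 dpi. Each response of the first kind set PVY arrays with the wider spread against mock arrays without it. In the second kind only the 6 dpi comparison of NahG-Rywal held arrays with the wider spread, all of them mock.

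**Figure D4:**
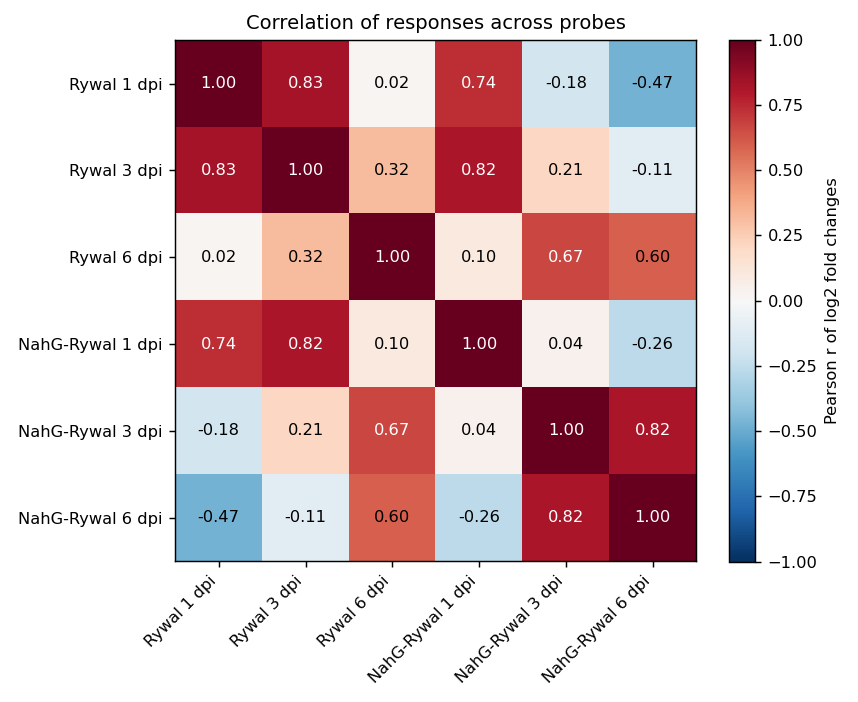
Pearson r across probes between the log2 fold changes of the 6 responses, each pair of responses resting on different arrays. The 3 responses of Rywal 1 dpi, Rywal 3 dpi and NahG-Rywal 1 dpi correlate at 0.74 to 0.83, and Rywal 1 dpi with NahG-Rywal 6 dpi at -0.47.

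A set of late rises was common to both genotypes. Of the 1143 probes that rose at least 2-fold in Rywal at 6 dpi, 964 also did so in NahG-Rywal at 6 dpi, against 135 for independent lists, and 798 in NahG-Rywal at 3 dpi, against 46. In the 964 probes the median response was 1.5 in Rywal (quartiles 1.19 and 2.09) and 3.1 in NahG-Rywal (2.13 and 4.4) at 6 dpi, the days on which they were chosen. At 3 dpi it was 1.34 in Rywal and 1.9 in NahG-Rywal, and 611 and 784 of the 964 rose at least 2-fold. At 1 dpi the medians were -0.09 and 0.38, with 89 and 54 probes up and 166 and 22 down at least 2-fold. Rises of at least 2-fold at both 3 and 6 dpi in both genotypes covered 523 probes. Of these, 104 had also risen by that much at 1 dpi in either genotype. Falls of at least 2-fold on both days in both genotypes covered 18 probes. STMIP09TV_659 belonged to the rises: at 1 dpi its response was 1.4 in Rywal (adjusted p = 9.9e-04) and 0.82 in NahG-Rywal (adjusted p = 6.2e-02), and at 6 dpi it was 7.61 in NahG-Rywal (adjusted p = 2.5e-20).

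Whether the response itself differed between the genotypes was tested as NahG-Rywal response minus Rywal response. At 1 dpi it differed for 10227 of 41450 probes, 5574 with a positive and 4653 with a negative difference, and by at least 2-fold for 1942. Some of these 10227 probes had also passed the tests of both responses. Among those with the same direction, the Rywal response was the larger for 3281 and the NahG-Rywal response for 155. Opposite directions were found for 540. Rises in Rywal with falls in NahG-Rywal made up 164 of them, against 2496 for independent lists, and the reverse 376, against 2575. STMCQ39TV_570 rose in Rywal (3.82) and fell in NahG-Rywal (-1.43), a difference of -5.25 (SE 0.43, adjusted p = 6.3e-11). MICRO.11003.C1_714 did the reverse (-1.81 and 1.96, difference 3.76, SE 0.32, adjusted p = 9.3e-11). With the 75th percentile set equal, 9008 differences were positive and 2807 negative.

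At 3 dpi the response differed for 23375 of 41464 probes, 10212 positive and 13163 negative, and by at least 2-fold for 9488. Of these 23375 probes, 5201 were called in both responses with opposite directions. Rises in Rywal with falls in NahG-Rywal made up 3378, against 3404 for independent lists, and the reverse 1823, against 1872. Among those called in both with the same direction, the Rywal response was the larger for 2095 and the NahG-Rywal response for 604. 054G12AF.esd_237 fell in Rywal (-4.3) and rose in NahG-Rywal (1.75), a difference of 6.05 (SE 0.85, adjusted p = 1.3e-07). Its NahG-Rywal mock mean of 10.53 ± 2.84 (SD, n = 4) was lowered by plant 1, at 6.287 (others 11.727 to 12.225), against 12.28 ± 0.23 in PVY leaves, so most of the rise came from that plant; without it the difference was 4.64 (adjusted p = 7.6e-15). MICRO.833.C4_18 rose in Rywal (4.54) and fell in NahG-Rywal (-0.91), a difference of -5.46 (SE 0.25, adjusted p = 1.1e-18). MICRO.6414.C1_647, which fell by 5 in Rywal, had a response of 0.26 in NahG-Rywal (adjusted p = 4.2e-01), a difference of 5.25. At this day the Rywal PVY arrays had the wider spread and the other 3 groups did not.

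At 6 dpi the response differed for 21098 of 41450 probes, 10259 positive and 10839 negative, and by at least 2-fold for 8253. Some of these 21098 probes had also been called in both genotypes. Among those with the same direction, in contrast to 1 dpi, the NahG-Rywal response was the larger for 4527 and the Rywal response for 136. Opposite directions were found for 1686. Rises in Rywal with falls in NahG-Rywal made up 671, against 2109 for independent lists, and the reverse 1015, against 2150. Only the NahG-Rywal mock arrays had the wider spread at 6 dpi, while at 1 dpi the PVY arrays of both genotypes had it. The split by the larger response was not recomputed with mock arrays replaced, so its contrast between the days may hold part of that shift. With the NahG-Rywal mock arrays replaced, 16925 probes differed. For MICRO.8335.C3_1111 the fit gave a difference of 6.9 (SE 0.73, adjusted p = 1.2e-09). In mock leaves at 6 dpi it was above background on 0 Rywal and 2 NahG-Rywal arrays, so its Rywal response, 1.04 (adjusted p = 1.4e-01), had only a bound, and neither the size of the difference nor its rank is settled. STMCK16TV_480 had the largest negative difference, -6.21 (SE 1.11, adjusted p = 1.2e-05), with responses of 1.51 in Rywal (adjusted p = 1.5e-01) and -4.69 in NahG-Rywal (adjusted p = 1.7e-06).

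The 1143 probes that rose at least 2-fold in Rywal at 6 dpi were followed as a set. Their median response at 6 dpi was 1.44 in Rywal and 2.74 in NahG-Rywal, and the median difference was 1.23 (quartiles 0.24 and 2.15). The difference passed its own test upward for 712 of them and downward for 122.

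Mock leaves of the genotypes were compared to see what the transgenic line changed without virus. At 1 dpi, 13742 of 41461 probes differed, 7029 higher and 6713 lower in NahG-Rywal. At 3 dpi, 16054 of 41465 differed, 8634 higher and 7420 lower, or 17193 and 6323 with the 75th percentile set equal. With the trend along the ID number removed, 7015 were higher and 9133 lower. At 6 dpi, 20462 of 41457 differed, 11463 higher and 8999 lower, or 7014 and 10607 with that scaling, and here the NahG-Rywal arrays had the wider spread. On all 3 days 2714 probes were higher in NahG-Rywal, against 405 for lists independent between days, and 2189 were lower, against 261. By at least 2-fold, 275 were higher and 381 lower on every day, against 1.2 and 2.5. A further 754 passed on all 3 days with a sign that differed between days.

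STDB003I03u.scf_35 had the largest mock difference on each day. At 1 dpi it averaged 6.34 ± 0.05 in NahG-Rywal and 14.69 ± 0.08 in Rywal mock leaves (SD, n = 4 each), a difference of -8.36 (SE 1.12, adjusted p = 2.4e-07), and the differences at 3 and 6 dpi were -8.2 and -7.86. SSBN001B09u.scf_149 was higher in NahG-Rywal by 3.74 at 1 dpi (SE 0.23, adjusted p = 2.6e-15) and by 4.15 at 6 dpi (SE 0.23, adjusted p = 5.2e-17). MICRO.7289.C2_67 was higher in NahG-Rywal at 3 dpi by 7.04 (SE 0.24, adjusted p = 2.7e-23), with 13.4 ± 0.09 against 6.36 ± 0.08 (SD, n = 4 each). Its mock differences at 1 and 6 dpi were 0.04 (adjusted p = 9.2e-01) and -0.33 (adjusted p = 2.5e-01). The largest positive difference at 1 dpi, that of MICRO.11.C2_1216 (3.81, adjusted p = 1.3e-02), lost its call with 1 fewer array while staying about as large: it was 3.27 (adjusted p = 5.4e-02) without mock plant 3 and 3.22 (adjusted p = 6.4e-02) without mock plant 4, over all alternatives 1.3e-03 to 6.4e-02.

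Change of the response over the 3 days was tested within each genotype. In Rywal, 25189 of 41447 probes had responses that differed between days, and in NahG-Rywal 27735 of 41457 did, or 28348 with the mock arrays of 6 dpi replaced. MICRO.6414.C1_647 ran from -4.39 at 1 dpi to -0.58 at 6 dpi (adjusted p = 6.2e-02) in Rywal, and from -2.61 to 2.55 in NahG-Rywal (adjusted p = 3.1e-11 and 5.5e-12). Its mock level in NahG-Rywal was 12.09 ± 0.03 at 1 dpi, 11.37 ± 0.29 at 3 dpi and 9.58 ± 0.13 at 6 dpi (SD, n = 4 each).

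The authors' deposited table of fold changes and adjusted p-values, with 33928 probes, was set beside the 6 responses. At an adjusted p below 0.05 the authors' deposited table held 12096 probes higher and 10212 lower in Rywal at 1 dpi, 12934 and 10891 at 3 dpi, and 4987 and 6130 at 6 dpi. For NahG-Rywal the authors' deposited table gave 9049 and 7272 at 1 dpi, 5591 and 8642 at 3 dpi, and 11129 and 13320 at 6 dpi. The log2 fold changes of the authors' deposited table correlated across probes with those fitted here at 0.975 to 0.982. Among probes called in both, 61 had opposite signs in NahG-Rywal at 1 dpi and 0 in the other 5 responses.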

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

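The tests of a shift not tied to the virus, of the virus as the only source, of exchanged genotype labels, and both tests on the authors' matrix were chosen only after the results they measure were seen, as were the settings with replaced mock arrays and with the number trend removed.

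The responses of Rywal at 1 and 3 dpi and of NahG-Rywal at 1 dpi correlated at 0.74 or more across probes, and the difference between NahG-Rywal mock leaves at 6 and 3 dpi, in which no virus was involved, correlated with them at 0.61, 0.66 and 0.75, against -0.26 to 0.29 for the 4 mock differences between days without the NahG-Rywal arrays of 6 dpi (all pairs without shared arrays). On the first principal component (36.3% of variance over 23894 probes) the mock arrays of NahG-Rywal at 6 dpi lay 38.2 above the highest other mock array, which argues against the virus as the only source of this profile. Removing the trend along the number that ends the probe IDs left the lowest correlation between the 3 responses at 0.73. This argues against that trend as the whole cause. Foreground values with only a common median gave 0.73 as well. They keep the wider spread of the PVY arrays, which by itself can make these responses alike. That result therefore does not decide on the quantile normalization. Over all 48 arrays as labelled, 9 probes kept the genotypes apart by over 1 (log2). Genotype labels were changed for 1 array, 1 array of each genotype, a group, or both genotypes of a day and inoculum. Every change left 0 such probes, except 4 when Rywal 1 dpi PVY plant 4 alone was changed. This argues against exchanged genotype labels as the source. An exchange of day or inoculum labels within a genotype would not alter that separation and was not tried. A shift between sets of leaves or arrays may therefore be part of these 3 responses and, with the sign turned, of the NahG-Rywal response at 6 dpi; the labels give no slide, scan date or hour of sampling that would tell sets of leaves from sets of arrays, and an early response to the inoculum stays open beside it.

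In the authors' matrix, 265 probes stood at the shared value 2.58 in 24 or more of the 48 columns, all of them in array rows 155 to 162. All of them, 100%, had zero weight on the array of Rywal 1 dpi PVY plant 1, while 80.8% were above background on 40 or more of the other 47 arrays, which argues against a lack of signal. A damaged area of that array, carried into the authors' values of other arrays, is a candidate explanation. The authors' deposited table lists 227 of these probes, with 0 called in 5 of the responses and 207 in NahG-Rywal at 1 dpi. The fit to the scanner values called 153, 174 and 84 of the 265 in Rywal at 1, 3 and 6 dpi and 129, 103 and 205 in NahG-Rywal.

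The 1143 probes that rose at least 2-fold in Rywal at 6 dpi rose further in NahG-Rywal, with a median difference of 1.23. With the NahG-Rywal mock arrays of 1 and 3 dpi in place of the 6 dpi ones the median difference was 1.4, and it was 1.35 with the 75th percentile set equal and 1.33 without background subtraction, which argues against the shifted mock arrays, the scaling and the background correction as its source. With the replaced mock arrays 69.2% of these probes passed the test of the genotype difference upward and 8.23% downward. At both 1 and 3 dpi, 626 probes were at least 2-fold lower in NahG-Rywal than in Rywal mock leaves, and 301 of them belong to the 1143. The replacing mock arrays are those same arrays, so these tests do not separate a lower starting level in NahG-Rywal from a stronger rise. A stronger late response in NahG-Rywal is a hypothesis from these values, found and tested on the same arrays, and 1 transgenic line cannot tell the loss of salicylic acid from other properties of that line.

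The response differed between the genotypes for 10227 probes at 1 dpi, 23375 at 3 dpi and 21098 at 6 dpi, and between days for 25189 probes in Rywal and 27735 in NahG-Rywal. Of the 4 probes named per response, the number whose response differed between the genotypes on that day was 4 in Rywal and 0 in NahG-Rywal at 1 dpi, 3 and 4 at 3 dpi, and 1 and 4 at 6 dpi. Over the days, 10 of 10 probes named for Rywal and 12 of 12 named for NahG-Rywal had responses that differed; these were chosen for their large changes.

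Chance as the source of the 14 counts was tested by regrouping the same arrays. In each case only 1 split, the real one, gave a count that high. This argues against chance for the responses and the mock leaves, each count taken alone. With 35 splits no smaller share than 1 in 35 is possible. For the genotype difference of the response and the change over time, the regrouping also mixed the genotypes or the inocula. It therefore does not decide on chance there, and the margin was small for the genotype difference at 1 dpi. Of 35 splits each, the highest other count was 14168 against 24139 for Rywal at 1 dpi, 15983 against 25595 at 3 dpi and 5305 against 12882 at 6 dpi, and 759 against 17619, 285 against 16762 and 13484 against 27662 for NahG-Rywal. For the mock leaves it was 7768 against 13742, 2731 against 16054 and 5604 against 20462 at 1, 3 and 6 dpi. Of 100 splits each, it was 9641 against 10227, 18447 against 23375 and 14826 against 21098 for the genotype difference of the response at 1, 3 and 6 dpi, and 18538 against 25189 and 22840 against 27735 for the change over time in Rywal and NahG-Rywal.

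Single plants stood apart from the other 3 of their group in 5 of 60 groups tested on array measures and in 10 of 113 groups tested on named probes (the groups that each probe's comparison uses, where all 4 plants had values); chance gives about 1 in 20. Rywal 3 dpi mock plant 1 had 1436 bright spots of zero weight (others 748 to 824). The median negative control intensity was 14.5 in Rywal 6 dpi mock plant 2 (others 13.3 to 13.5) and 7.49 in NahG-Rywal 1 dpi PVY plant 2 (others 11.3 to 11.9). The mean spike-in level was 9.52 (log2) in Rywal 1 dpi mock plant 2 (others 8.96 to 9). The upper spread was 2.59 in Rywal 1 dpi PVY plant 3 (others 2.74 to 2.76). Among normalized log2 levels, bf_cswcxxxx_0005c09.t3m.scf_66 was at 9.2 in NahG-Rywal 1 dpi mock plant 1 (others 6.924 to 7.266). MICRO.15720.C1_569 was at 6.762 in NahG-Rywal 1 dpi PVY plant 4 (others 6.899 to 6.923). MICRO.9396.C1_1045 was at 6.926 in NahG-Rywal 3 dpi mock plant 3 (others 6.112 to 6.221) and at 13.54 in PVY plant 2 (others 12.89 to 12.98). SDBN003C07u.scf_513 was at 7.079 in NahG-Rywal 6 dpi PVY plant 1 (others 7.736 to 7.772). STMCQ39TV_570 was at 11.05 in NahG-Rywal 1 dpi PVY plant 4 (others 11.89 to 12.03). 054G12AF.esd_237 was at 6.287 in NahG-Rywal 3 dpi mock plant 1 (others 11.73 to 12.23). MICRO.1995.C3_54 was at 8.557 in NahG-Rywal 3 dpi PVY plant 2 (others 9.062 to 9.135). PPCBO67TH_550 was at 6.869 in Rywal 6 dpi PVY plant 3 (others 6.157 to 6.267). STDB003I03u.scf_35 was at 7.3 in NahG-Rywal 6 dpi mock plant 3 (others 6.356 to 6.487).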

How the results depend on the processing

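The 14 counts were recomputed under 297 combinations of comparison and alternative, of which 3 moved a count by over 1.5 times. With the 75th percentile of each array set equal, the count for NahG-Rywal at 3 dpi was 25485, against 16762; the cause was not tested. With only the 8 arrays compared in the fit, the count for Rywal at 6 dpi was 7101, against 12882. The same setting also lowered the Rywal counts at 1 and 3 dpi, to 18203 and 23898. It raised those of NahG-Rywal to 21189, 18064 and 29240 at 1, 3 and 6 dpi. Fewer arrays behind the spread therefore do not by themselves account for the change, and its cause was not tested. With only the 23894 probes above background on all arrays, the count for NahG-Rywal at 6 dpi was 18201, against 27662, with fewer probes tested. The settings with that filter, with bright spots of zero weight kept, with mock arrays replaced and with the number trend removed were chosen after seeing the data.

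The 75th percentile scaling moved the median of all probes from 0.03 to -0.23, 0.03 to -0.11 and -0.02 to -0.19 for Rywal at 1, 3 and 6 dpi, and from 0.04 to 0.15, -0.03 to -0.32 and -0.02 to -0.3 for NahG-Rywal. It moved that median from 0 to 0.31 and from -0.05 to -0.24 for the genotype difference of the response at 1 and 3 dpi, and from 0.01 to 0.23 and 0.03 to -0.18 for mock leaves at 3 and 6 dpi. The share of higher calls then changed from 54.9% to 38.9% and 55.2% to 44% for Rywal at 1 and 3 dpi, from 55.7% to 49.6%, 40.4% to 20.5% and 45.5% to 34.4% for NahG-Rywal at 1, 3 and 6 dpi, from 54.5% to 76.2% for the genotype difference of the response at 1 dpi, and from 53.8% to 73.1% and 56% to 39.8% for mock leaves at 3 and 6 dpi. With the number trend removed, the share went from 45.1% to 52.2% for Rywal at 6 dpi, from 55.7% to 49.7%, 40.4% to 50.3% and 45.5% to 50.5% for NahG-Rywal at 1, 3 and 6 dpi, from 43.7% to 51.3% and 48.6% to 52.3% for the genotype difference of the response at 3 and 6 dpi, and from 51.1% to 50% and 53.8% to 43.4% for mock leaves at 1 and 3 dpi. With the mock arrays replaced it went from 48.6% to 50.4% for the genotype difference of the response at 6 dpi. Removing the number trend centres each array within bins of ID number and mean level, which by itself favours an even balance. The shares under that setting therefore do not decide on the balance. Because the shares also changed with the scaling, the balance of rises and falls over all calls is not settled by these values.

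Leaving out 1 array at a time gave 22682 to 24253 probes for Rywal at 1 dpi, 24390 to 25209 at 3 dpi and 10754 to 12635 at 6 dpi, and 15870 to 16262, 14126 to 15764 and 26468 to 27040 for NahG-Rywal. The genotype difference of the response ranged over 8246 to 12520, 22471 to 23104 and 19931 to 21136 at 1, 3 and 6 dpi, and the difference in mock leaves over 11072 to 15335, 14150 to 15154 and 18814 to 19759. Change over time ranged over 24093 to 26333 in Rywal and 26921 to 27630 in NahG-Rywal. Of 898 values of named probes under alternatives, 0 changed sign and 3 passed the threshold no longer, each with 1 plant left out: bf_cswcxxxx_0005c09.t3m.scf_66 without NahG-Rywal 1 dpi PVY plant 1 (1.82, adjusted p = 8.5e-02, over alternatives 2.2e-03 to 8.5e-02), and MICRO.11.C2_1216 without Rywal 1 dpi mock plant 3 (3.27, adjusted p = 5.4e-02) or plant 4 (3.22, adjusted p = 6.4e-02, over alternatives 1.3e-03 to 6.4e-02).

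Plants that share a number across inocula did not deviate together: 6 of 24 pairs correlated above 0.1, over a range of -0.61 to 0.37, and 10 of 48 plants matched their own number best, so the numbers do not pair the plants. With the plant number as a replicate block, 23302, 24854 and 11922 probes were called for Rywal at 1, 3 and 6 dpi and 16536, 15776 and 27000 for NahG-Rywal, and no count moved by over 1.5 times. Not run were a slide or scan date as a block, since the files give none, and the collapse of probes with the same description and the estimated correlation within gene lists, since the files give no descriptions. Signal over background limits what can be seen, since 79.4% to 93.5% of probes per array were above background.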

Other observations

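Probes that distinguished the genotypes without virus were followed into the PVY leaves. At both 1 and 3 dpi, 626 probes were at least 2-fold lower and 525 at least 2-fold higher in NahG-Rywal than in Rywal mock leaves. In the 6 dpi responses, which share no array with that choice, the lower ones rose with PVY in both genotypes: 301 of the 626 (48.1%) rose at least 2-fold in Rywal, against 2.76% of all probes, and 450 (71.9%) in NahG-Rywal, against 11.8%. Their median response was 0.97 in Rywal and 2.25 in NahG-Rywal. Of the 525 probes that were higher in NahG-Rywal mock leaves, 413 (78.7%) fell at least 2-fold in NahG-Rywal at 6 dpi, against 12.3% of all probes, while in Rywal 11 fell and 21 rose by that much, with a median of -0.11. The mean signed deviation of the 1151 probes (positive as in NahG-Rywal mock leaves) was 0.82 ± 0.06 in NahG-Rywal mock leaves and -1.28 ± 0.09 in NahG-Rywal PVY leaves at 6 dpi (log2, SD, n = 4 each). In Rywal it was -0.41 ± 0.29 and -1.05 ± 0.23. In Rywal at 1 dpi, with mock arrays that took part in the choice, the probes went the other way: of the 626, 231 fell and 7 rose at least 2-fold, of the 525, 265 rose and 4 fell, and the mean deviation was -1.04 ± 0.45 in mock and -0.07 ± 0.33 in PVY leaves. In Rywal at 3 dpi, 222 of the 626 rose and 101 fell, and 116 of the 525 rose and 20 fell. In NahG-Rywal at 3 dpi, 57.5% of the 626 rose, against 4% of all probes, and 24.6% of the 525 fell, against 1.79%. At 1 dpi, 35 of the 626 (5.59%) rose, against 0.666% of all probes, and 34 fell, against 4.96%. Of the 525, 26 (4.95%) fell, against 4.96%, and 9 rose. The mock arrays of all 1 and 3 dpi responses took part in the choice. That alone favours rises of the 626 in NahG-Rywal and falls of them in Rywal, and the reverse for the 525. The PVY arrays of Rywal at 1 and 3 dpi and of NahG-Rywal at 1 dpi and the mock arrays of NahG-Rywal at 6 dpi are the 16 with the wider spread, so these responses may hold part of that shift.

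A few probes switched between a low and a high level; most of the low levels of STDB003I03u.scf_35 and MICRO.7289.C2_67 were still above background. STDB003I03u.scf_35 was above 13 on 21 of 24 Rywal arrays and below 8 on all 24 NahG-Rywal arrays. The 3 Rywal exceptions were all PVY plants, 1 dpi plant 4 at 8.09, 3 dpi plant 4 at 8.13 and 6 dpi plant 3 at 7.54. All 3 lay above the highest NahG-Rywal array, at 7.3, while the lowest of the other Rywal plants stood at 13.89. Of these, Rywal 1 dpi PVY plant 4 was also the only Rywal array with a mean signed deviation above 0 (0.295), and 4 probes set it with NahG-Rywal while 9 set it with Rywal. MICRO.7289.C2_67 averaged 13.4 ± 0.09 in mock and 12.7 ± 0.19 in PVY leaves of NahG-Rywal at 3 dpi, and 6.36 to 7.49 in the other 10 groups. PPCBO67TH_550 averaged 12.85 ± 0.27 in NahG-Rywal PVY leaves at 6 dpi and 7.92 ± 0.51 at 3 dpi (SD, n = 4 each), and 6.1 to 6.39 in the other 10 groups, in several of which it was not well above background on most arrays.

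Spots without an ID gave no signal. Of these 1769 spots, 0 had a median ratio of foreground to background over 1.5. The highest was 1.27, against 1.32 among negative controls.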
